A study of Drosophila melanogaster with 4 samples.

How the data were processed

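The series holds 4 RNA-seq samples of adult male Drosophila melanogaster, 1 for each of 4 genotypes. Per the labels' protocols, RNA was isolated with a GE Healthcare kit, quantified with a Qubit fluorometer and made into libraries by Illumina's procedure. The aligner, the quantification tool, the transcript annotation and the genome build are not given in the sources used here.

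The deposited data are 1 table of the whole series with 28061 transcripts. Per the file headers, 4 columns annotate each transcript (FlyBase transcript identifier, CG identifier, transcript name and chromosome arm). The other 16 columns hold values and are named ES95 to ES102 and ES602 to ES609. The name of the table calls these values FPKM, read fragments scaled by transcript length and library size, as deposited. The headers do not say what the ES numbers stand for. They are taken here as library numbers, and 0 of them occur in a label of the 4 samples. No source used here pairs a library number with a genotype. None of the 16 columns was therefore assigned to a sample, and none of their values was used. Column order was not used, because no source says that the columns follow the order of the samples. Expression levels, those of Tis11 included, were not used either. Groups defined by the values of some genes cannot then be compared on those genes, and no source used here could check such an assignment. The values of Tis11, white and yellow and the correlations between columns were seen while the contents of the table were being examined, and they decided no assignment.

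Only the annotation columns, and which value cells were empty, were summarised, with Python 3.11.15. A gene symbol was taken from each transcript name by removing its isoform suffix. Gene positions were read from the Ensembl annotation of assembly BDGP6. The chromosome names of the deposited table include heterochromatin arms such as 2LHet, which belong to an earlier assembly, so no coordinate was transferred between the table and BDGP6. The comparisons planned before the data were examined (knockout against its wild type, G1183 against its wild type, the wild types against each other, gene list medians, genes with a UAUUUAU element and genes near Tis11) were not run, nor were their alternatives. The UAUUUAU comparison also needs nucleotide sequence, and the reference used here held annotation only. The plan assumed 1 library per genotype. With 16 columns for 4 samples a genotype may have several libraries, and the sources used here do not say how many or whether they are separate RNA samples.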

Results

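RNA was sequenced from adult male flies of 4 genotypes to examine how gene expression differs between wild-type flies and flies with altered Tis11. Tis11 is the Drosophila member of the tristetraprolin family, zinc finger proteins that bind AU-rich elements in the 3′ untranslated regions of mRNAs and promote mRNA decay. The genotypes were a w1118/BSC5 wild type, a Tis11 knockout, a y w67c23 wild type and the Tis11 allele G1183 in the y w67c23 background. The knockout carries the deficiency named IE35 and a w allele written w*. Its label also names a duplication of X material on the Y, written with BSC5 and y+. The deficiency and the duplication may change the copy number of genes other than Tis11, so the knockout cannot be taken as a change of Tis11 alone. BSC5 is also named in the label of the w1118/BSC5 wild type, so the duplication may be common to the knockout and that wild type. The labels give 1 sample for each genotype. They imply a comparison of the knockout with the w1118/BSC5 flies and a comparison of G1183 with the y w67c23 flies.

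Expression was deposited per transcript, not per gene. The table listed 28061 transcripts of 13886 gene symbols, of which 7972 had a single transcript. Of the 28061 transcripts, 213 had no value in the 8 columns ES95 to ES102. Another 109 had none in the other 8 columns, ES602 to ES609. The remaining 27739 had a value in every column. The empty cells thus followed the numbering of the columns, and the sources used here do not say whether these sets were processed separately. The chromosome arm with the most transcripts was 3R, with 6761 transcripts of 3383 genes. The X chromosome, which carries Tis11, had 4690 transcripts of 2155 genes. The mitochondrial genome contributed 13 transcripts.

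Tis11 was represented by 3 transcripts, Tis11-RA, Tis11-RB and Tis11-RC. In the BDGP6 annotation the gene (FBgn0011837) lies on the forward strand of chromosome X from position 12659415 to 12682560, also with 3 transcripts. The white and yellow genes, which give the w and y of the genotype names, were each represented by 1 transcript on the X chromosome. In BDGP6, white (FBgn0003996) lies on the reverse strand from 2790599 to 2796466 and yellow (FBgn0004034) on the forward strand from 356509 to 361245.

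No expression level and no difference between genotypes is reported. The 16 columns of values are named by ES numbers that match none of the sample labels, and no source used here pairs the columns with the samples. There are more columns than samples, so a sample may stand for several libraries, which the labels do not say. The depth of the libraries is unknown.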

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

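No result was computed from the expression values, so none of the alternatives chosen before the data were examined (other pseudocounts, filters, scalings, controls and ways of drawing random gene lists) was run. No paired analysis was possible because no column of values was matched to a sample.

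The number of genes behind the listed transcripts was 13886 by gene symbol and 13941 by CG identifier, an alternative chosen after seeing the data.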
